A study of Mus musculus with 12 samples.

How the data were processed

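Mammary tumours of BALB/c mice were profiled by RNA sequencing. The tumours grew from 300000 cells of 4T1, a metastatic mouse mammary carcinoma line that carries firefly luciferase here, injected into the mammary fat pad number 4. Per the labels, treatment began 14 days after injection and lasted 2 weeks. The groups were vehicle, MBQ-167 at 100 mg/kg given 5 times a week, paclitaxel at 5 mg/kg given 1 time a week, and the combination of both drugs. MBQ-167 is described by the submitters as an inhibitor of the small GTPases Rac and Cdc42, and paclitaxel is a drug that stabilises microtubules. The mice were killed on day 28, and each group holds 3 libraries named as biological replicates. Whether each library is a separate mouse is not stated, so p-values measure the spread between these libraries. The labels mention 2 occasions of cell injection without saying which library belongs to which, so occasion and group cannot be told apart.

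The deposited values are raw counts per gene in 1 column per library. The submitters' processing notes name HISAT2 for alignment to GRCm38, HTSeq for counting and DESeq2 for their own tests. Their tool versions, the annotation version, the strandedness of the libraries and the treatment of reads that map to several places are not given in the sources used here. The labels call the molecule polyA RNA. Every value was checked to be a whole number of 0 or more. The table lists 46078 genes, of which 15275 had no count in any of the 12 libraries, and 45143 of the identifiers matched a symbol. Gene coordinates, biotypes and transcript GC content came from GENCODE vM21 on GRCm38. Total counts ran from 11540557 to 17001562 per library, of which 52.67% to 71.54% fell in protein-coding genes.

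Genes were kept by the filterByExpr function of edgeR with its minimum count of 10, which left 18252 genes. A quasi-likelihood model of edgeR 4.0.16 with TMM scaling was fitted to all 12 libraries, with a biological coefficient of variation of 0.214 and 8 residual degrees of freedom. Fold changes are on the log2 scale with their standard error (SE), and n is 3 per group throughout. Each comparison was adjusted by the Benjamini-Hochberg method over all genes, and a gene passed the test at an adjusted p under 0.05. There were 6 comparisons: each drug group against vehicle, the combination against each single drug, and the interaction, which is combination minus MBQ-167 minus paclitaxel plus vehicle and is 0 where the effects add on the log2 scale. CPM values are counts scaled by edgeR to the TMM-corrected library size, given as mean ± SD. Exact permutation tests are two-sided. With 3 libraries against 3 such a test cannot fall below 0.1.

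Before the data were examined, 37 gene lists were written, and the comparisons, the threshold, the rule for named genes and most alternatives were fixed. The lists cover central carbon metabolism, lipid metabolism, the drug targets, proliferation, stress, immune responses and cell types that a tumour sample may hold. Lists with at least 4 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with a correlation estimated from the data, and fry, which asks whether a list moves one way on balance without comparing it with other genes, was run beside it. The lists of secretory mammary markers and lung epithelial markers had 3 tested members each and were not tested. List counts are given over all genes and adjusted over the list alone. The value given for a list is the median log2 fold change of its tested members.

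The rule for named genes took, among genes with a mean of at least 1 CPM and no overlap between the libraries of the groups compared, the 8 largest changes in each direction that passed the test against vehicle. It took 5 per direction in the other comparisons, or the 3 smallest p-values per direction where no gene passed. It added the 4 members with the smallest p-values of each list that passed and 11 genes fixed in advance: Rac1, Cdc42, Pak1, Hk2, Ldha, Pkm, G6pdx, Cs, Phgdh, Tubb5 and Mki67. Other genes named singly were chosen after their values were seen. These are Klf2 and Fkbp5 in the interaction, Jun, Egr1, Junb and Nr4a1 among the immediate early genes, the other genes that passed in all 3 comparisons with vehicle, and the members of lists added later.

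The alternatives fixed in advance were DESeq2 1.42.0, limma voom, RLE size factors, no filter on low counts, a stricter filter of 1 CPM in 3 libraries, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were a per-library correction for GC content, made as an offset from a spline with 5 degrees of freedom for the 18144 genes with a GC value, a fit of protein-coding genes only, the neutrophil marker level as a covariate, and 4 further lists (heat shock, glucocorticoid-induced, circadian output and zinc finger genes), which were adjusted over these 4 and again over all 39 lists tested. The labels name no litter, day or animal that a replicate number stands for, but vehicle and combination libraries with the same number deviated together from their group means (correlations of 0.11, 0.22 and 0.19), so a fit with both the block and the GC correction was added for that comparison. Fold changes that share the same vehicle libraries are correlated by construction. That correlation was measured on 20 simulated sets in which no group differed. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.

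The pipeline was tested on simulated data built from these libraries with 200 changed genes. Of 67 genes changed 2-fold, 41.8% were found in the MBQ-167 comparison, 47.8% in the paclitaxel comparison and 16.4% in the interaction. Of 67 genes changed 1.5-fold, 10.4%, 7.46% and 4.48% were found. False calls were 4, 7 and 4 genes. With no gene changed, there were 0 to 1 calls per comparison. A GC trend of a size set by hand was also simulated, together with 200 changed genes. It gave 648 false calls in the paclitaxel comparison, or 85.7% of its calls, and 9 after the GC correction. A list changed as a whole was found in all 6 comparisons at the preset correlation, and with an estimated correlation only in the MBQ-167 comparison. No list that was left unchanged passed, 0 of 34. These lists held random genes simulated independently, so they do not show how often lists of related genes pass without a change. Other splits of pairs of the real groups gave 6 to 22 lists at the preset correlation.

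Genes with near-identical copies are less certain, since the handling of shared reads is not given. These include Hba-a1 and Hba-a2, Hbb-bs, the stefins such as Stfa2l1, Trbc1 and Trbc2, Hspa1b, and Gapdh, Aldoa, Ldha, Pkm, Actb and the tubulins with their pseudogenes. Genes that overlap on opposite strands are uncertain for the same reason. No gene was removed for this. Spike-in controls are not named in the labels, so all changes are relative to the other genes of a library.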

Results

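Gene expression was measured in 12 tumour libraries, 3 from each of the vehicle, MBQ-167, paclitaxel and combination groups. Total counts were 16025318, 14119192 and 16419510 in vehicle libraries 1 to 3, and 13947914, 14752255 and 15746272 in the MBQ-167 libraries. They were 17001562, 12310300 and 15785555 in the paclitaxel libraries and 11540557, 15239296 and 16120018 in the combination libraries. A share of 17.11% to 37.54% of the counts fell on 3 features that lie together on chromosome 17 (GRCm38): the lincRNA genes Gm26917 (39843013 to 39846341) and Gm42418 (39846958 to 39848788), and CT010467.1 (39846353 to 39848827), annotated as ribosomal RNA. Their share was 34.6% ± 2.95 (SD, n = 3) in vehicle, 32.6% ± 3.64 in MBQ-167, 25.7% ± 7.72 in paclitaxel and 28.1% ± 8.82 in combination libraries. The 9 drug libraries had 28.8% ± 6.86, and an exact two-sided permutation test over 220 splits of vehicle against them gave p = 0.182. CT010467.1 alone, a small part of that share, was higher in all 3 vehicle libraries (1.42% ± 0.499, at least 1.111%) than in the 9 drug libraries (0.463% ± 0.273, at most 0.8664%; exact permutation p = 0.00455 over 220 splits, a test chosen after the values were seen). Its group means were 0.397%, 0.314% and 0.678% with MBQ-167, paclitaxel and the combination. Gm26917 (exact permutation p = 0.423) and Gm42418 (exact permutation p = 0.0682) overlapped between vehicle and drug libraries.

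Libraries also differed in how expression varied with the GC content of transcripts. The correlation across genes between GC content and the deviation of a gene's log2 CPM from its mean was 0.213 ± 0.098 (SD, n = 3) in vehicle, 0.0663 ± 0.073 in MBQ-167, -0.213 ± 0.0902 in paclitaxel and -0.117 ± 0.0809 in combination libraries. Vehicle differed from the 9 drug libraries, at -0.0878 ± 0.142, in an exact two-sided permutation test over 220 splits (p = 0.0136). Across genes, the log2 fold change against vehicle had a Spearman correlation with GC content of -0.193 for MBQ-167, -0.397 for paclitaxel and -0.333 for the combination. Genes are not independent replicates, so no p is given for these. The neutrophil marker level also set 1 library apart: it was 1.43 in vehicle 3 and -0.588 and -0.839 in vehicle 1 and 2, in mean log2 CPM around the vehicle mean.

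**Figure D1:**
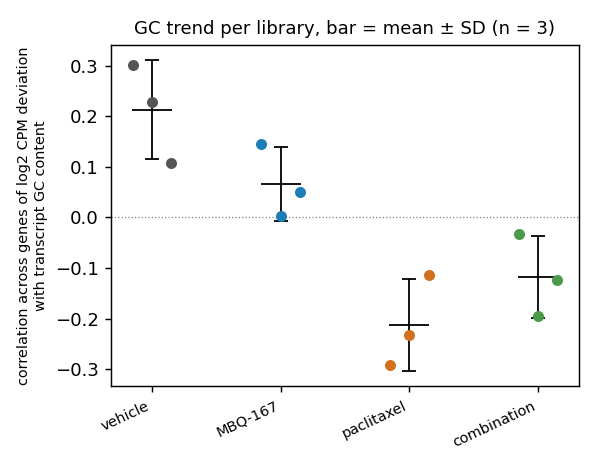
Correlation across genes between transcript GC content and the deviation of log2 CPM from the gene's mean, 1 point per library, with mean ± SD bars (n = 3 per group). Vehicle libraries averaged 0.213 and paclitaxel libraries -0.213.

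The first comparison asks what MBQ-167, given alone, changed in the tumours. Immediate early genes, which are transcribed within minutes of a stimulus, were lower in the MBQ-167 tumours. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), a subunit of the transcription factor AP-1, fell from 57.1 ± 10.3 CPM (SD, n = 3) in vehicle to 11 ± 1.22 CPM, a log2 fold change of -2.38 ± 0.23 (SE, adjusted p = 0.000843). Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), another AP-1 subunit, fell from 42.7 ± 9.6 to 4.81 ± 1.88 CPM (-3.16 ± 0.40, adjusted p = 0.00475). Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039), a transcription factor induced by stress, changed by -2.03 ± 0.22 (adjusted p = 0.0016), and Dusp1 (ENSMUSG00000024190, chromosome 17, 26505590 to 26562128), a phosphatase that switches off MAP kinases, by -1.46 ± 0.16 (adjusted p = 0.0016). In each of these genes all 3 MBQ-167 libraries lay below all 3 vehicle libraries. The list of 13 immediate early genes fell with a median of -0.70. Of its members 4 fell over all genes tested and 10 when adjusted over the list alone, and the list passed with camera (adjusted p = 7.62e-25; adjusted p = 0.00831 with an estimated correlation).

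**Figure D2:**
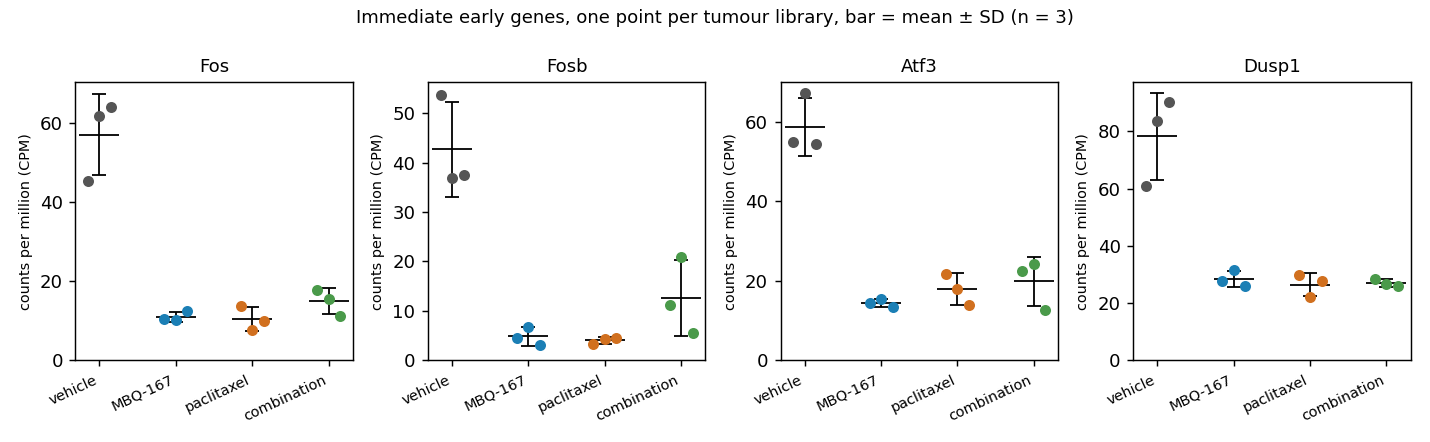
Expression in CPM of Fos, Fosb, Atf3 and Dusp1 in each tumour library, with mean ± SD bars (n = 3 per group). Fos lay between 45.3 and 64.1 CPM in vehicle libraries and between 7.51 and 17.8 CPM in the 9 drug libraries.

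In total 17 genes passed, 3 higher and 14 lower. Besides the immediate early genes, the lower ones included Klf2 (-1.36 ± 0.17), a transcription factor of quiescent lymphocytes and endothelium, Jund (-1.24 ± 0.20), an AP-1 subunit, Ppp1r15a (-1.24 ± 0.18), which targets a phosphatase to the translation factor eIF2α, and Tcim (-1.11 ± 0.14). The higher ones were Tmem229b (0.82 ± 0.13, adjusted p = 0.0254), from 15 ± 1.67 to 26.5 ± 2.11 CPM, and the transcripts Gm38253 (1.45 ± 0.23) and 4930404I05Rik (1.15 ± 0.18). Jund lies within a locus shared with Gm11175 on the opposite strand, and with the strandedness unknown their counts may mix. Fos, Atf3, Dusp1 and Klf2 passed in each of 6 fits that left out 1 library. Fosb missed the threshold without MBQ-167 library 3 (-2.91, adjusted p = 0.0568) and Tcim without MBQ-167 library 2 (-1.12). Ppp1r15a missed it without each MBQ-167 library in turn (-1.26, -1.27 and -1.19 without libraries 1, 2 and 3), and Jund in those fits (-1.24, -1.27 and -1.23) and without vehicle 1 (-1.06). Tmem229b passed in 1 of the 6 fits, without vehicle 2. Gm38253 passed only without vehicle 3 and missed the threshold after the GC correction (1.07), while 4930404I05Rik passed without MBQ-167 library 1 and without vehicle 2. The number of genes was 12, 5 and 5 without MBQ-167 libraries 1, 2 and 3, and 10, 42 and 14 without vehicle libraries 1, 2 and 3.

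Some lists of central carbon metabolism were lower in the MBQ-167 tumours by camera at the preset correlation, though no single member of these lists passed over all genes. Glycolysis genes fell with a median of -0.40 over 17 members, of which 0 passed over all genes and 11 fell when adjusted over the list alone (camera adjusted p = 3.12e-11; adjusted p = 0.149 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, had -0.76 ± 0.15 (adjusted p = 0.0793) and Pfkl, a phosphofructokinase, -0.50 ± 0.13 (adjusted p = 0.142). Nuclear genes of oxidative phosphorylation fell (median -0.31, 4 of 37 adjusted over the list alone, adjusted p = 0.241 with an estimated correlation), as did pyruvate dehydrogenase and TCA cycle genes (-0.21, 0 of 24 alone, adjusted p = 0.162 with an estimated correlation) and fatty acid oxidation genes (-0.24, 1 of 16 alone, adjusted p = 0.259 with an estimated correlation). Without vehicle 1 the medians of oxidative phosphorylation and fatty acid oxidation were -0.21 and -0.11. The pentose phosphate list had a median of -0.18 and did not pass (adjusted p = 0.0599). The serine and one-carbon list (-0.13) and the glutamine list (-0.16) did not pass either.

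Genes of the drug target pathway changed little. The mRNAs of the targets Rac1 (-0.18 ± 0.12, adjusted p = 0.555) and Cdc42 (-0.09 ± 0.13, adjusted p = 0.825) and of their effector kinase Pak1 (-0.03 ± 0.15, adjusted p = 0.96) did not pass, and the list of 32 Rac and Cdc42 signalling genes fell with a median of -0.13 (0 members passed over all genes and 0 adjusted over the list alone; camera adjusted p = 0.0159; adjusted p = 0.408 with an estimated correlation). Without MBQ-167 library 2 that call was lost (median -0.09), as it was without vehicle 2 (-0.11). Actin and Arp2/3 genes fell (median -0.30, 1 of 21 adjusted over the list alone, adjusted p = 0.162 with an estimated correlation), and tubulins fell (-0.21, 0 of 16 alone, adjusted p = 0.302 with an estimated correlation; -0.32 without vehicle 2). Targets of the actin-dependent factor SRF had a median of -0.17 and did not pass. Mki67, a marker of dividing cells, had -0.09 ± 0.14 (adjusted p = 0.843).

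Stress and immune lists moved as well. Hypoxia genes fell (median -0.47, 8 of 16 adjusted over the list alone, adjusted p = 0.169 with an estimated correlation; -0.30 without MBQ-167 library 3), and so did genes of the unfolded protein and integrated stress response (-0.31, 5 of 14 alone, adjusted p = 0.0809 with an estimated correlation). Interferon response genes rose with a median of 0.44, 8 of 28 adjusted over the list alone and 0 over all genes (adjusted p = 0.276 with an estimated correlation); the median was 0.29 without vehicle 3. Neutrophil markers fell with a median of -1.77, 14 of 20 adjusted over the list alone and 0 over all genes (adjusted p = 0.241 with an estimated correlation); without vehicle 3, whose neutrophil level stood apart, the median was -0.59. Erythroid markers fell (-1.65, 2 of 7 alone, adjusted p = 0.276 with an estimated correlation). The T and NK cell list (0.64, 0 of 19 alone, adjusted p = 0.444 with an estimated correlation) and the antigen presentation list (0.45, 1 of 16 alone, adjusted p = 0.496 with an estimated correlation) rose. Without vehicle 3 both calls were lost, with medians of 0.27 and 0.18. With the neutrophil marker level as a covariate the T and NK cell median was -0.03 and did not pass (adjusted p = 0.922). In the same fit the interferon median was 0.26. The T and NK cell median was 1.06 without vehicle 1, and the antigen presentation median 0.18 without MBQ-167 library 1.

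The second comparison asks what paclitaxel alone changed. The immediate early genes were lower here too: Fos changed by -2.44 ± 0.23 (SE, n = 3 per group, adjusted p = 0.000594), Fosb by -3.43 ± 0.41 (adjusted p = 0.00198), Atf3 by -1.71 ± 0.22 and Dusp1 by -1.56 ± 0.16. The list fell with a median of -0.84, with 7 of 13 members over all genes (4 with the neutrophil marker level as a covariate) and 10 adjusted over the list alone (camera adjusted p = 1.86e-19; adjusted p = 0.0194 with an estimated correlation). The other members that fell were Jun (-0.95), Zfp36 (-0.84), which marks short-lived mRNAs for decay, and Nr4a1 (-1.20), an orphan nuclear receptor.

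Glycolysis genes fell in the paclitaxel tumours with a median of -0.49, 9 of 17 over all genes (4 after the GC correction) and 13 adjusted over the list alone (camera adjusted p = 1.8e-12; adjusted p = 0.115 with an estimated correlation). Slc2a1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983) fell from 303 ± 13.1 CPM (SD, n = 3) to 159 ± 20.4 CPM (-0.93 ± 0.15, adjusted p = 0.00488), and Pfkl (ENSMUSG00000020277, chromosome 10, 77986947 to 78010083) from 322 ± 24.4 to 191 ± 3.65 CPM (-0.75 ± 0.13, adjusted p = 0.00682). Both passed in each of 6 fits that left out 1 library. Aldoa, the muscle-type aldolase, changed by -0.69 ± 0.13 (adjusted p = 0.0118), Hk1, a hexokinase, by -0.64 ± 0.13, Pkm, pyruvate kinase, by -0.51 ± 0.13 (adjusted p = 0.0311) and Ldha, lactate dehydrogenase A, by -0.49 ± 0.14 (adjusted p = 0.0492). Without paclitaxel library 2 Aldoa had an adjusted p of 0.0545 (-0.66) and Hk1 missed the threshold (-0.56), as Hk1 did without paclitaxel library 1 (-0.63). Pkm passed only without vehicle 3 and Ldha in 0 of the 6 fits, with values between -0.57 and -0.43. After the GC correction Ldha (-0.45) and Pkm (-0.44) also missed the threshold. Hk2 had -0.35 ± 0.14 (adjusted p = 0.14), and G6pdx, the entry enzyme of the pentose phosphate pathway, -0.47 ± 0.15 (adjusted p = 0.0755).

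**Figure D3:**
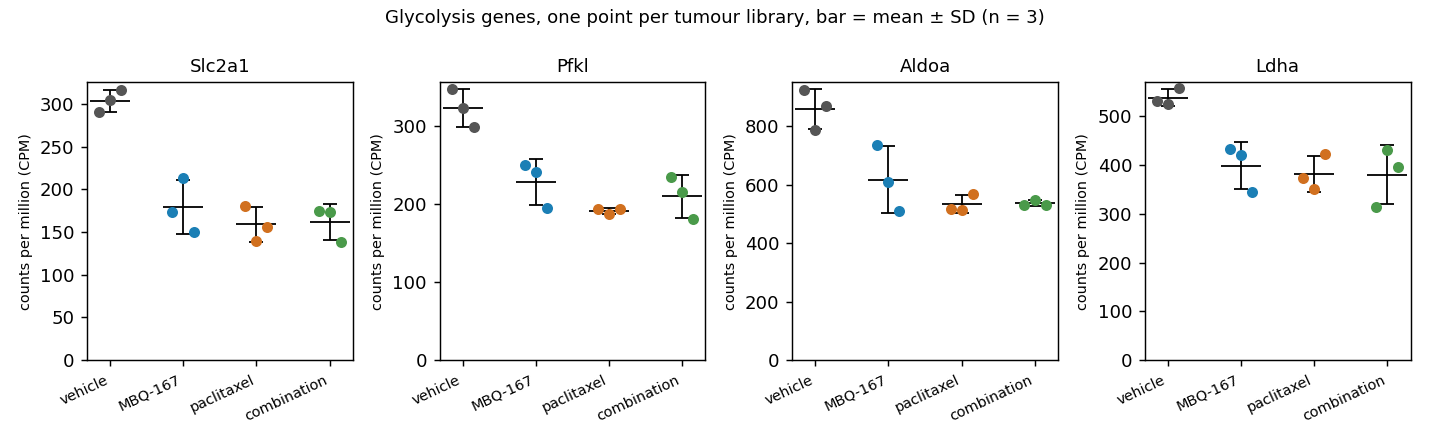
Expression in CPM of Slc2a1, Pfkl, Aldoa and Ldha in each tumour library, with mean ± SD bars (n = 3 per group). Slc2a1 lay between 290 and 316 CPM in vehicle libraries and between 138 and 213 CPM in the 9 drug libraries.

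Lists of nuclear genes for mitochondrial metabolism were lower as well in the paclitaxel tumours, while mitochondrially encoded transcripts had a median of 0.30 and did not pass (adjusted p = 0.0527). After the GC correction the mitochondrially encoded transcripts turned to -0.398 and passed (camera adjusted p = 0.0297). TCA cycle genes fell (median -0.24, 3 of 24 over all genes and 4 adjusted over the list alone, adjusted p = 0.263 with an estimated correlation), with Cs, citrate synthase, at -0.52 ± 0.11 (adjusted p = 0.0196). Oxidative phosphorylation genes fell (-0.30, 3 of 37 and 5 alone, adjusted p = 0.295 with an estimated correlation; -0.16 without vehicle 1), with Cox4i1 at -0.67 ± 0.15. Fatty acid oxidation genes fell (-0.15, 1 of 16 and 2 alone, adjusted p = 0.478 with an estimated correlation), a call lost without paclitaxel 1 (-0.15), paclitaxel 2 (-0.15) and vehicle 1 (-0.09) and with protein-coding genes only (-0.14), and moved to -0.24 without vehicle 3. Cholesterol synthesis genes fell (-0.36, 1 of 20 and 4 alone, adjusted p = 0.29 with an estimated correlation). The pentose phosphate list had a median of -0.26 (adjusted p = 0.0601), serine and one-carbon genes -0.21 and glutamine supply genes -0.21, and these lists did not pass. Phgdh, the entry enzyme of serine synthesis, had -0.01 ± 0.26 (adjusted p = 0.983). Cs and Cox4i1 missed the threshold without paclitaxel 1 (-0.43 and -0.56), paclitaxel 2 (-0.54 and -0.63) and vehicle 1 (-0.46 and -0.59).

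Interferon response genes rose in the paclitaxel tumours with a median of 0.85. Of 28 members 17 rose over all genes and 25 when adjusted over the list alone (camera adjusted p = 8.02e-22; adjusted p = 0.136 with an estimated correlation). Over all genes 9 rose after the GC correction and 2 with the neutrophil marker level as a covariate. Zbp1, a sensor of nucleic acids, rose by 1.45 ± 0.16 (adjusted p = 0.00198), Ifi44 by 1.41 ± 0.20 and Oasl2 by 1.11 ± 0.19. These 3 genes passed in each of 6 fits that left out 1 library. Ido1, an interferon-induced enzyme that breaks down tryptophan, rose by 2.60 ± 0.55 (adjusted p = 0.0164) and Klrd1, a receptor subunit of NK cells, by 2.93 ± 0.61 (adjusted p = 0.016). Both missed the threshold without paclitaxel 2 (1.94 and 2.67), and Klrd1 after the GC correction (2.28). The antigen presentation list rose (0.19, 1 of 16 over all genes and alone, adjusted p = 0.651 with an estimated correlation), with Nlrc5, an activator of MHC class I genes, at 1.06 ± 0.21. The T and NK cell list rose (0.81, 0 of 19, adjusted p = 0.567 with an estimated correlation). Without vehicle 3 the medians were -0.03 and 0.39 and neither list passed, nor did either without paclitaxel 2 (0.19 and 0.41). With the neutrophil marker level as a covariate the T and NK cell median was -0.25 and did not pass (adjusted p = 0.254). The antigen presentation median was 0.50 without vehicle 2, and Nlrc5 missed the threshold without paclitaxel 2 (0.86) and vehicle 1 (1.03).

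Neutrophil markers fell in the paclitaxel tumours with a median of -2.59, 13 of 20 over all genes and 16 adjusted over the list alone (camera adjusted p = 1.9e-13; adjusted p = 0.232 with an estimated correlation). Among the largest falls were Cd177 (-4.40 ± 0.83, adjusted p = 0.0107), a neutrophil surface protein, Ngp (-4.15 ± 0.87), a granule protein, Mmp8 (-3.80 ± 0.86), the neutrophil collagenase, and S100a8 (-2.57 ± 0.48), a subunit of calprotectin. Without vehicle 3 the median was -1.43, and Cd177, Ngp, Mmp8 and S100a8 had -2.59, -2.45, -1.37 and -1.53. Without paclitaxel 2 Cd177 (-4.22), Ngp (-3.92) and S100a8 (-2.38) missed the threshold, as Ngp did without paclitaxel 3 (-3.79). Mmp8 missed it without paclitaxel 1, 2 and 3 (-4.04, -3.80 and -3.61) and without vehicle 3. Erythroid markers fell with a median of -2.40, 3 of 7 over all genes and 6 adjusted over the list alone (adjusted p = 0.178 with an estimated correlation; -3.94 without paclitaxel 1). Hba-a1, an α-globin gene, had -2.22 ± 0.51 (adjusted p = 0.0237). It had -3.54 without paclitaxel 1 and missed the threshold without paclitaxel 2 (-1.83), paclitaxel 3 (-1.91) and vehicle 1 (-2.32).

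**Figure D4:**
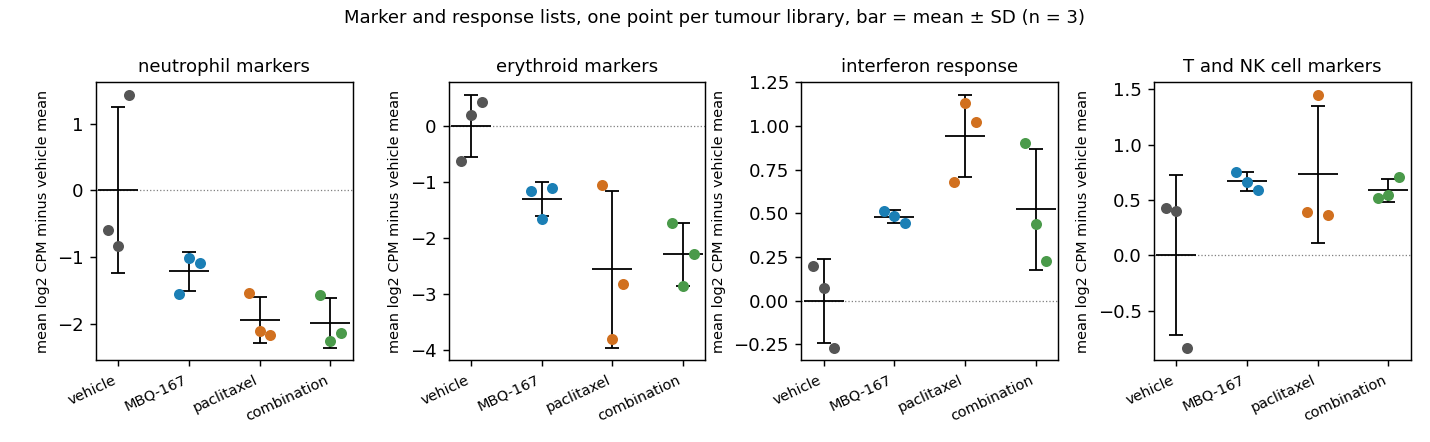
Mean log2 CPM of neutrophil markers, erythroid markers, interferon response genes and T and NK cell markers in each library, relative to the vehicle mean, with mean ± SD bars (n = 3 per group). Vehicle 3 has a neutrophil level of 1.43, against -0.588 and -0.839 in the other vehicle libraries.

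Stress, cytoskeletal and matrix genes also fell with paclitaxel. Hypoxia genes fell (median -0.41, 6 of 16 over all genes and alone, adjusted p = 0.263 with an estimated correlation; -0.26 without vehicle 2; 2 members over all genes after the GC correction and 0 with the neutrophil marker level as a covariate), led by Slc2a3, the glucose transporter GLUT3 (-1.78 ± 0.28, adjusted p = 0.00488). Genes of the unfolded protein and integrated stress response fell (-0.36, 3 of 14 and 6 adjusted over the list alone, adjusted p = 0.115 with an estimated correlation), with Ddit4, an inhibitor of mTORC1 (-1.02 ± 0.17), and Ddit3, the transcription factor CHOP (-0.97 ± 0.17). Actin and Arp2/3 genes fell (-0.36, 4 of 21 and 12 alone, adjusted p = 0.136 with an estimated correlation), with Arpc1b, an Arp2/3 subunit, at -0.57 ± 0.11. Tubulins and microtubule regulators, the class paclitaxel binds to or acts on, fell (-0.29, 3 of 16 and 5 alone, adjusted p = 0.263 with an estimated correlation), with Tubb5 at -0.50 ± 0.13 (adjusted p = 0.0364). The Rac and Cdc42 list fell (-0.20, 1 of 32 and 3 alone, adjusted p = 0.29 with an estimated correlation). Rac1 (-0.29 ± 0.12, adjusted p = 0.155), Cdc42 (-0.28 ± 0.13, adjusted p = 0.199) and Pak1 (0.01 ± 0.15, adjusted p = 0.971) did not pass. Slc2a3, Ddit4 and Ddit3 passed in each of 6 fits that left out 1 library. Arpc1b missed the threshold without paclitaxel 2 (-0.55), and Tubb5 passed only without vehicle 2 and not after the GC correction.

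Matrix genes fell in the paclitaxel tumours (median -0.28, 2 of 20 over all genes and alone, adjusted p = 0.623 with an estimated correlation), with Col6a1, a chain of collagen VI, at -1.02 ± 0.19 (adjusted p = 0.00955). Without vehicle 3 the median was 0.03 and without paclitaxel 3 it was -0.18, and neither fit kept the call; it was -0.42 without vehicle 1. Targets of SRF fell by camera (-0.32, 1 of 15 higher and 1 lower over all genes, 1 higher and 3 lower alone, adjusted p = 0.651 with an estimated correlation), with Ankrd1, a stretch-responsive protein, higher (0.80 ± 0.16) and Ccn1, a matrix-associated growth regulator, lower (-0.78 ± 0.21). That call was lost without paclitaxel 2 (-0.28), paclitaxel 3 (-0.25), vehicle 1 (-0.36) and vehicle 3 (-0.19), with RLE factors (-0.33), the GC correction (-0.29) and protein-coding genes only (-0.31), and the median was -0.51 without vehicle 2. Ccn1 missed the threshold without paclitaxel 1 (-0.79), paclitaxel 2 (-0.61) and vehicle 3 (-0.48) and after the GC correction (-0.73). The mitosis list had a median of 0.09, with 2 of 22 members higher over all genes, and did not pass (adjusted p = 0.144). Mki67 had 0.19 ± 0.14 (adjusted p = 0.464).

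In all, 1033 genes passed against vehicle in paclitaxel tumours, 578 higher (56.0%) and 455 lower. After the per-library GC correction 491 passed, 154 higher (31.4%) and 337 lower. Of these, 150 higher and 226 lower genes were among the calls made without correction. Among 4540 genes with the lowest GC content 431 were higher and 16 lower, and among 4525 genes with the highest 15 were higher and 208 lower. The count was 406, 230 and 707 without paclitaxel libraries 1, 2 and 3, and 366, 849 and 1139 without vehicle libraries 1, 2 and 3. Of 63 named genes that passed, 17 did so without paclitaxel 2, 36 without paclitaxel 1 and 37 without vehicle 1.

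The third comparison asks what both drugs together changed against vehicle. Immediate early genes fell with a median of -0.94, 9 of 13 over all genes and 11 adjusted over the list alone (camera adjusted p = 9.49e-24; adjusted p = 0.0099 with an estimated correlation). Over all genes 5 members fell after the GC correction and 2 with the neutrophil marker level as a covariate. Fos changed by -1.95 ± 0.22 (SE, n = 3 per group, adjusted p = 0.00387), to 14.9 ± 3.33 CPM, Dusp1 by -1.54 ± 0.16 (adjusted p = 0.0021), Atf3 by -1.58 ± 0.22 and Zfp36 by -1.10 ± 0.18. Egr1 (-0.94), Jun (-0.77) and Junb (-0.51), transcription factors induced by growth factors, fell too. Zfp36 missed the threshold without combination 1 (-1.12) and combination 2 (-1.13), and the first 3 passed in each of 6 fits that left out 1 library.

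Glycolysis genes fell in the combination tumours with a median of -0.51, 7 of 17 over all genes (1 after the GC correction) and 15 adjusted over the list alone (camera adjusted p = 9.14e-18; adjusted p = 0.0665 with an estimated correlation). Slc2a1 fell to 162 ± 20.9 CPM (-0.91 ± 0.15, adjusted p = 0.0146) and passed in each of 6 fits that left out 1 library. Aldoa (-0.68 ± 0.13, adjusted p = 0.0278), Pfkl (-0.62 ± 0.13, adjusted p = 0.0302) and Slc16a3, a lactate transporter (-0.70 ± 0.15), fell as well, but each missed the threshold without any 1 of the combination libraries or without vehicle 1, with values between -0.78 and -0.53, and after the GC correction. Pfkl (-0.62) and Slc16a3 (-0.59) also missed it without vehicle 2. Ldha (-0.50 ± 0.14, adjusted p = 0.0729), Pkm (-0.51 ± 0.13, adjusted p = 0.0551), Hk2 (-0.48 ± 0.14, adjusted p = 0.0792), G6pdx (-0.53 ± 0.15, adjusted p = 0.0779) and Cs (-0.38 ± 0.11, adjusted p = 0.0955) did not pass. The pentose phosphate list fell (median -0.34, 0 of 9 over all genes, 4 lower and 1 higher alone, adjusted p = 0.157 with an estimated correlation). TCA cycle genes (-0.22, 0 of 24 and 3 alone, adjusted p = 0.18 with an estimated correlation; -0.14 without vehicle 1), oxidative phosphorylation genes (-0.25, 0 of 37 and 0 alone, adjusted p = 0.27 with an estimated correlation) and cholesterol synthesis genes (-0.39, 0 of 20 and 6 alone, adjusted p = 0.235 with an estimated correlation) fell. Fatty acid oxidation genes fell (-0.13, 0 of 16 and 0 alone, adjusted p = 0.414 with an estimated correlation), a call lost without vehicle 1 (-0.02); the median was -0.25 without vehicle 3.

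Hypoxia genes fell in the combination tumours (median -0.42, 4 of 16 over all genes, 1 after the GC correction, and 7 adjusted over the list alone, adjusted p = 0.157 with an estimated correlation), with Slc2a3 at -1.83 ± 0.28 (adjusted p = 0.012) and Car9, a carbonic anhydrase induced by low oxygen, at -0.89 ± 0.17. Stress response genes fell (-0.26, 1 of 14 and 3 alone, adjusted p = 0.157 with an estimated correlation), a call lost without combination 3 (-0.14). Actin and Arp2/3 genes fell (-0.34, 2 of 21 and 11 alone, adjusted p = 0.157 with an estimated correlation), as did tubulins (-0.33, 1 of 16 and 2 alone, adjusted p = 0.167 with an estimated correlation) and Rac and Cdc42 genes (-0.17, 1 of 32 and 2 alone, adjusted p = 0.252 with an estimated correlation; -0.27 without combination 2). Cfl1, the actin-severing protein cofilin, fell by 0.53 on the log2 scale. Rac1 (-0.28 ± 0.12, adjusted p = 0.218), Cdc42 (-0.29 ± 0.13, adjusted p = 0.23), Pak1 (-0.33 ± 0.15, adjusted p = 0.249), Tubb5 (-0.42 ± 0.13, adjusted p = 0.101), Phgdh (-0.03 ± 0.26, adjusted p = 0.973) and Mki67 (0.11 ± 0.14, adjusted p = 0.728) did not pass. Targets of SRF fell by camera (-0.21, 1 of 15 and 2 alone, adjusted p = 0.597 with an estimated correlation). That call was lost without combination 1 (-0.05), combination 2 (-0.05), vehicle 1 (-0.19) and vehicle 3 (-0.04), after the GC correction (-0.14) and with protein-coding genes only (-0.19), and the median was -0.54 without combination 3. Slc2a3 missed the threshold without combination 1 (-1.71) and combination 2 (-1.81). Car9 and Cfl1 did so without any 1 of the combination libraries or without vehicle 1, Car9 between -0.96 and -0.85 and Cfl1 between -0.59 and -0.48, and after the GC correction (-0.84 and -0.48).

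Among immune and blood cell lists, neutrophil markers fell with a median of -2.61, 10 of 20 over all genes (5 after the GC correction) and 17 adjusted over the list alone (adjusted p = 0.157 with an estimated correlation), with S100a9, a calprotectin subunit, at -2.57 ± 0.42 (adjusted p = 0.0157) and Ngp at -4.25 ± 0.89. Without vehicle 3 the median was -1.31 and Ngp had -2.50, with an adjusted p of 0.0643. Erythroid markers fell (-2.58, 3 of 7 and 7 alone, adjusted p = 0.157 with an estimated correlation). Interferon response genes rose with a median of 0.54, 1 of 28 over all genes and 14 adjusted over the list alone (adjusted p = 0.27 with an estimated correlation), with Zbp1 at 1.00 ± 0.16 (adjusted p = 0.0146). Without combination 1 the median was 0.25 and Zbp1 missed the threshold (0.81). The T and NK cell list rose (0.84, 0 of 19, adjusted p = 0.553 with an estimated correlation), but not without vehicle 3 (0.36), and the median was 0.51 without combination 1. With the neutrophil marker level as a covariate neither the interferon list (0.27, adjusted p = 0.0821) nor the T and NK cell list (-0.19, adjusted p = 0.0927) passed. Klrd1 rose by 2.77 ± 0.61 (adjusted p = 0.0388). S100a9 missed the threshold without combination 1 (-2.69) and combination 2 (-2.52), and Ngp also without combination 1, 2 and 3 (-5.56, -3.78 and -3.87). Klrd1 missed it without combination 1, 2 and 3 (2.83, 2.57 and 2.89) and without vehicle 1 (2.21), and both Ngp and Klrd1 after the GC correction.

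In total 336 genes passed in the combination tumours, 188 higher and 148 lower. After the GC correction 74 passed, 18 higher (24.3%) and 56 lower. The count was 29, 38 and 82 without combination libraries 1, 2 and 3, and 60, 246 and 416 without vehicle libraries 1, 2 and 3. Of 39 named genes that passed, 5, 7 and 11 did so without combination libraries 1, 2 and 3.

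In all 3 drug groups 14 genes passed against vehicle in the same direction. They were lower for Fos, Fosb, Atf3, Dusp1, Klf2, Klf6, Ppp1r15a, Tcim, Fkbp5, Cited2, Nfil3 and Serpinb6a, and higher for Gm38253 and 4930404I05Rik. Paclitaxel and MBQ-167 tumours compared directly, which was not among the 6 planned comparisons, gave 0 genes with edgeR. There were 1256 at an unadjusted p under 0.05, and the smallest adjusted p was 0.375.

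The comparisons share their vehicle libraries, which alone makes them alike. The log2 fold changes of MBQ-167 and paclitaxel correlated across 18252 genes with r = 0.768 and a covariance of 0.231, against 0.51 ± 0.0102 and 0.0821 in 20 simulated sets with no drug effect. MBQ-167 and the combination gave 0.742 and 0.209, against 0.504 ± 0.0116 and 0.0815. Paclitaxel and the combination gave 0.823 and 0.274, against 0.509 ± 0.00826 and 0.0819. Genes shared by MBQ-167 and paclitaxel were 3 higher and 13 lower, where independent calls would share 0.095 and 0.349. MBQ-167 and the combination shared 2 higher and 12 lower, against 0.0309 and 0.114, and paclitaxel and the combination 171 higher and 119 lower, against 5.95 and 3.69. The most genes shared in any of the 20 simulated sets were 0, 1 and 0 for these pairs. With no drug effect hardly any gene passes, so that count was low by construction and is no measure of the sharing. The simulated genes were drawn independently. Shifts of many genes together in a vehicle library are thus missing from the simulated correlations, which may be too low. No gene passed in opposite directions, 0 in each pair. With 3 vehicle libraries the controls cannot be divided between comparisons, so part of the excess may come from them.

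The fourth comparison, of the combination with MBQ-167, asks what paclitaxel added to MBQ-167. By camera at the preset correlation 5 lists were lower in the combination tumours, those of lipid synthesis among them. Every other split of these libraries gave more lists, 8 to 16, so these falls may be chance. With fry or an estimated correlation 0 lists passed. Cholesterol synthesis genes fell (median -0.29, 0 of 20 over all genes and 3 adjusted over the list alone, camera adjusted p = 1.97e-08; adjusted p = 0.405 with an estimated correlation), among them Insig1, which holds back the cholesterol sensor SCAP, at -0.50 ± 0.12 (adjusted p = 0.879). Fatty acid synthesis genes fell (-0.13, 0 of 13 and 2 alone, adjusted p = 0.106 with an estimated correlation; -0.27 without combination 3), among them Scd2, a desaturase, at -0.52 ± 0.14. Glycolysis genes fell (-0.15, 0 of 17 and 0 alone, camera adjusted p = 0.000272; adjusted p = 0.98 with an estimated correlation; -0.06 without MBQ-167 library 1 and -0.23 without library 3). Neutrophil (-0.92, 0 of 20 and 0 alone) and erythroid markers (-0.98, 0 of 7 and 0 alone) fell, each with an adjusted p = 0.98 with an estimated correlation. The erythroid call was lost without combination 2 (-0.81), and its median was -1.49 without combination 1. No single gene passed with edgeR: 0 of 18252, 940 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma voom. The smallest adjusted p, 0.879, was shared by Rev3l, the catalytic subunit of a translesion DNA polymerase (0.54 ± 0.12), and Rn7sk, the 7SK RNA (0.54 ± 0.12).

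The fifth comparison, of the combination with paclitaxel, asks what MBQ-167 added to paclitaxel. Interferon response genes were lower in the combination tumours (median -0.42, 0 of 28 over all genes and 1 adjusted over the list alone, camera adjusted p = 1.5e-19; adjusted p = 0.377 with an estimated correlation; -0.64 without combination 1), with Ifi44 at -0.78 ± 0.20 (SE, adjusted p = 1.0). Cytokine genes fell (-0.36, 0 of 22 and 1 alone, adjusted p = 0.3 with an estimated correlation), with Il10 at -2.07 ± 0.54 and Il1b at -0.76 ± 0.23, both with an adjusted p of 1.0. Keratinocyte markers rose (1.25, 0 of 8 and 0 alone, adjusted p = 0.377 with an estimated correlation; 0.80 without combination 1, 0.81 without paclitaxel 1 and 3.03 without paclitaxel 3). Matrix genes rose (0.21, 0 of 20 and 0 alone, adjusted p = 0.998 with an estimated correlation), a call lost without combination 3 (-0.06) and paclitaxel 3 (0.11); the median was 0.37 without combination 1. Skeletal muscle markers rose (0.51, 0 of 15 and 0 alone, adjusted p = 0.999 with an estimated correlation), a call lost without combination 1 (0.59), combination 3 (0.34), paclitaxel 1 (0.40) and paclitaxel 2 (0.45) and after the GC correction (0.51), with 1.05 without paclitaxel 3. Mitochondrially encoded transcripts fell (-0.28, 0 of 13 and 0 alone, adjusted p = 0.998 with an estimated correlation), a call lost without combination 1 (-0.13) and after the GC correction (-0.17), with -0.48 without combination 3. In all 6 lists passed by camera at the preset correlation and 0 with fry or an estimated correlation. Every other split of these libraries gave at least as many, up to 18, so these list changes may be chance. No gene passed with edgeR: 0 of 18252, 430 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma voom. Among the smallest p-values were Tnfrsf19, a receptor of the TNF receptor family (0.90 ± 0.18), Per2, a circadian clock gene (1.09 ± 0.23), and Ankrd1 (-0.73 ± 0.16), each with an adjusted p of 1.0.

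The interaction asks whether the effects of both drugs add on the log2 scale. Several immediate early genes departed from that. Vehicle is part of this contrast, so a shift of the vehicle libraries alone would give a positive value for genes that are lower in all 3 drug groups. Fos had an interaction of 2.88 ± 0.32 (SE, n = 3 per group, adjusted p = 0.00514) and Fosb of 4.81 ± 0.56 (adjusted p = 0.00514), beside changes of -3.16, -3.43 and -1.77 for Fosb in MBQ-167, paclitaxel and combination tumours. Positive interactions were found also for Atf3 (2.17 ± 0.31), Jund (1.90 ± 0.28), Klf2 (1.65 ± 0.24), Dusp1 (1.49 ± 0.22), Gm11175 (1.73 ± 0.28) and Fkbp5 (1.36 ± 0.21), a co-chaperone of the glucocorticoid receptor. Ch25h, an interferon-induced enzyme that makes 25-hydroxycholesterol, had -3.04 ± 0.48, with 2.17 ± 1.28 CPM in vehicle, 8.12 ± 1.44 and 8.02 ± 2.05 CPM with MBQ-167 and paclitaxel, and 3.63 ± 0.687 CPM with the combination. Zbp1 (-1.37 ± 0.23) and Tmem229b (-1.19 ± 0.18) were negative too. In all 11 genes passed, 8 positive and 3 negative, and 1795 had an unadjusted p under 0.05. The immediate early list was positive (median 0.43, 4 of 13 over all genes and 6 adjusted over the list alone, adjusted p = 0.0373 with an estimated correlation). Fos and Fosb passed in all 20 alternative fits, Klf2 in 15, Dusp1 in 14, Atf3 and Jund in 13, Fkbp5 in 11, Ch25h and Tmem229b in 10, Zbp1 in 9 and Gm11175 in 8 of its 19. The count was 15, 2 and 11 without combination libraries 1, 2 and 3, 5, 2 and 2 without MBQ-167 libraries, 5, 5 and 2 without paclitaxel libraries, and 4, 16 and 9 without vehicle libraries 1, 2 and 3.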

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

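The tests of the immediate early genes, the glycolysis genes and the higher paclitaxel calls with the GC correction, the fit of protein-coding genes only, the relation of the GC trend to the ribosomal share and the sorting of other splits by their vehicle libraries were chosen only after the results they concern were seen. The tests with the neutrophil level, the heat shock genes and the zinc finger genes and all counts of other splits were written down before their results.

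Immediate early genes fell in all 3 drug groups. After the GC correction the median closest to 0 was -0.682. The adjusted p with an estimated correlation was 0.00956, 0.0229 and 0.0114 for MBQ-167, paclitaxel and the combination. This argues against the GC trend as the whole cause. With the neutrophil marker level as a covariate the median closest to 0 was -0.571. The list passed at the preset correlation in all 3 comparisons both times, a setting at which other splits of the libraries also gave many lists. Over all genes 4, 7 and 5 members passed after the correction and 4, 4 and 2 with the covariate, against 4, 7 and 9. With the covariate the adjusted p with an estimated correlation was 0.0702, 0.222 and 0.207. The median SE of the list's members grew from 0.18, 0.18 and 0.182 to 0.225, 0.283 and 0.288. The neutrophil level varied within groups mostly among vehicle libraries, so that fit cannot decide on fewer neutrophils. Stress of the vehicle tumours at collection, which the labels do not describe, cannot be told apart from a drug effect: heat shock genes were lower too, with -0.225 as the median closest to 0, while across the 12 libraries within groups they followed the immediate early genes with r = 0.242 (exact permutation p = 0.559 over 1296 permutations, adjusted p = 0.559), rho = 0.245 (exact permutation p = 0.551, adjusted p = 0.551) and r = 0.142 without the 2 farthest libraries, in a family of 2 relations. An effect of the drugs on these genes is a hypothesis that may hold besides, found and tested on the same data.

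Glycolysis genes fell in all 3 drug groups. After the GC correction the median closest to 0 was -0.382, with 0, 4 and 1 members past the threshold for MBQ-167, paclitaxel and the combination against 0, 9 and 7 before, and an adjusted p with an estimated correlation of 0.189, 0.116 and 0.0956. With the neutrophil marker level as a covariate the median closest to 0 was -0.465 (adjusted p = 0.263, 0.283 and 0.287 with an estimated correlation), and 0, 1 and 0 members passed, as the median SE grew from 0.136 in each comparison to 0.172, 0.215 and 0.221. The list passed at the preset correlation in all 3 comparisons both times, but some other splits of the libraries gave at least as many lists at that setting. The GC-corrected medians were -0.382, -0.442 and -0.455, against -0.4, -0.493 and -0.511 before. This argues against the GC trend as the whole cause. With the covariate the medians were -0.465, -0.677 and -0.638. The neutrophil level varied within groups mostly among vehicle libraries (SD 1.24, against 0.293, 0.347 and 0.373), so that fit cannot decide on fewer neutrophils. A lower share of other glycolytic cells and a direct effect of the drugs may both stay open, and neither was tested.

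Genes that were higher in paclitaxel tumours outnumbered those that were lower, 578 against 455. After the GC correction 154 were higher and 337 lower, so the excess went with GC content. The correction also removes a drug effect that follows GC, so the source cannot be told. The excess stayed with protein-coding genes only, without the 3 chromosome 17 features. That fit gave 515 higher, or 3.76% of the genes tested against 3.17% with all genes, and 382 lower. It cannot judge the share of these features as a mark of library quality. Why libraries differ in their GC trend cannot be told apart: within groups it went with the ribosomal share at r = 0.432 (exact permutation p = 0.246, adjusted p = 0.492), rho = 0.455 (exact permutation p = 0.224, adjusted p = 0.448) and r = 0.159 without the 2 farthest of 12 libraries. Zinc finger genes, which are poor in GC, had a median of 0.245 over 317 genes in paclitaxel tumours, 47 higher and 2 lower. After the correction it was 0.118, with 7 and 2, so part of their rise went with GC.

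For 11 genes the interaction test passed: Fos 2.88, Fosb 4.81, Atf3 2.17, Klf2 1.65, Jund 1.90, Dusp1 1.49, Fkbp5 1.36, Gm11175 1.73, Tmem229b -1.19, Ch25h -3.04 and Zbp1 -1.37. The test asks whether the effect of 1 drug differs with the other present, but a shift of the vehicle libraries alone enters it too and gives a positive value where all 3 drug groups are about equally low, as for Dusp1 (-1.46, -1.56 and -1.54). In the combination against either single drug 0 genes passed. Among the 35 lists written in advance the same test passed for 20 at the preset correlation and for 1 of them, the immediate early genes (median 0.432), with an estimated correlation. The positive lists were oxidative phosphorylation (0.337), neutrophil markers (1.80), actin and Arp2/3 (0.345), glycolysis (0.35), the unfolded protein and integrated stress response (0.417), pyruvate dehydrogenase and TCA cycle (0.243), hypoxia (0.361), erythroid markers (1.36), fatty acid oxidation (0.217), fibroblast and matrix markers (0.37), epithelial markers (0.694), skeletal muscle markers (1.01), tubulins (0.319) and Rac and Cdc42 signalling (0.0918). The negative ones were interferon response (-0.757), antigen presentation (-0.458), T and NK cell markers (-0.74), mitochondrially encoded transcripts (-0.282) and inflammatory cytokines (-0.322). The 15 positive lists had medians below 0 in each drug group against vehicle. Interferon response, antigen presentation and T and NK cell markers had medians above 0, and mitochondrially encoded transcripts and inflammatory cytokines had medians of both signs. The 4 lists added after the results were seen passed at the preset correlation: glucocorticoid-induced (0.93), heat shock (0.424), zinc finger (-0.167) and circadian output genes (0.172). With an estimated correlation none passed when adjusted over all 39 lists (p = 0.0546, 0.148, 0.272 and 0.375), and over the 4 alone the first 2 did (0.0168 and 0.0304). With GC corrected the medians were 0.885, 0.466, -0.0482 and 0.183, and the circadian call over 39 lists was lost. The zinc finger median was -0.0988 without paclitaxel 1. The circadian call was lost without vehicle 1 (0.126), MBQ-167 library 3 (0.0792) and paclitaxel 3 (0.104), and its median was 0.265 without MBQ-167 library 2 and 0.3 without paclitaxel 1.

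Calls of 10 of these 20 lists at the preset correlation were lost when 1 library was left out. Without vehicle 3 these were T and NK cell markers (-0.427), antigen presentation (-0.187), epithelial (0.343), fibroblast (0.0594) and skeletal muscle markers (-0.407), inflammatory cytokines (-0.306) and tubulins (0.247). Without vehicle 1 they were epithelial markers (0.49), fatty acid oxidation (0.134), mitochondrially encoded transcripts (-0.0989) and tubulins (0.266), and without vehicle 2 Rac and Cdc42 signalling (0.0919). Without MBQ-167 library 1 they were epithelial (0.453) and skeletal muscle markers (0.677). Without MBQ-167 library 2 they were Rac and Cdc42 signalling (0.0809), epithelial markers (0.617), cytokines (-0.222), mitochondrially encoded transcripts (-0.327) and tubulins (0.31). Without MBQ-167 library 3 they were Rac and Cdc42 signalling (0.0946) and skeletal muscle markers (0.656). Paclitaxel library 1 did this for epithelial markers (0.561) and cytokines (-0.255), and paclitaxel library 2 for Rac and Cdc42 signalling (0.0824), T and NK cell markers (-0.139), skeletal muscle markers (0.83) and tubulins (0.252). Combination library 1 did so for epithelial markers (0.579), cytokines (-0.294) and mitochondrially encoded transcripts (-0.0231), and combination library 2 for Rac and Cdc42 signalling (0.0955) and tubulins (0.261). Combination library 3 did so for antigen presentation (-0.152), epithelial (0.604), fibroblast (0.121) and skeletal muscle markers (0.829) and tubulins (0.245). After the GC correction the calls of mitochondrially encoded transcripts (0.0683), epithelial (0.628) and skeletal muscle markers (1.05) and tubulins (0.32) were lost, and with protein-coding genes only that of Rac and Cdc42 signalling (0.0848).

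Other interaction medians moved by over 1.5 times and kept their call. Neutrophil markers had 0.482 without vehicle 3, erythroid markers 2.67 without paclitaxel 1, and hypoxia 0.224 without combination 2 and 0.214 without MBQ-167 library 3. Antigen presentation had -0.892 without combination 1 and -0.224 without MBQ-167 library 1, and fibroblast markers 0.246 without paclitaxel 3. Rac and Cdc42 signalling had 0.195 without MBQ-167 library 1, 0.145 without paclitaxel 1 and 0.138 without paclitaxel 3. Mitochondrially encoded transcripts had -0.606 without combination 3, -0.182 without paclitaxel 1 and -0.598 without vehicle 3, and skeletal muscle markers 2.28 without MBQ-167 library 2 and 1.56 without vehicle 2.

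Other splits of the same libraries into groups of the same size give a measure of chance. For each pair of groups there are 10 splits, too few for a share under 0.05. At least as many genes as in the real split came from 1 of 10 splits for MBQ-167 against vehicle (17 genes, highest other 1), 1 for paclitaxel (1033, highest other 0), 1 for the combination (336, highest other 2), 10 for the combination against MBQ-167 (0, highest other 0) and 10 for the combination against paclitaxel (0, highest other 5). At least as many lists came from 4 splits for MBQ-167 (17 lists, highest other 21), 3 for paclitaxel (18, highest other 22), 3 for the combination (18, highest other 21), 10 for the combination against MBQ-167 (5, highest other 16) and 10 for the combination against paclitaxel (6, highest other 18). For the interaction 3 of 100 splits, the real one among them, gave at least 11 genes, and the highest other split gave 45. Such splits mix drug and vehicle libraries within groups, which widens the spread. They do not hold the drug effects fixed, so chance cannot be excluded for that count. What gave 45 genes in that split was not found. Among the other splits the 21 with all 3 vehicle libraries on 1 side of the contrast gave at most 5 genes. The split with 45 had 2 vehicle libraries on 1 side. For the interaction lists 16 of 100 splits gave at least 20, with 26 as the highest other, so chance cannot be excluded there either.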

How the results depend on the processing

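The GC correction, alone or with the block, the fit of protein-coding genes only and the neutrophil covariate were chosen after seeing the data, and the other alternatives were fixed in advance; the cause of a difference was not tested unless stated. Of 124 passing values of genes named by the rule, or of Klf2 and Fkbp5 in the interaction, all kept their call with RLE factors. So did 122 of 122 with the stricter filter, 120 of 120 with DESeq2 and 122 of 124 with no filter. With protein-coding genes only 106 of 109 did, with limma voom 95 and with the GC correction 78. With only the groups compared, and so fewer libraries to estimate the spread, 29 of 111 did. No named value reversed. Leaving out vehicle 1, 2 or 3 kept 66, 100 and 95 of the 124. Against vehicle, leaving out drug library 1, 2 or 3 kept 7, 5 and 5 of 11 for MBQ-167. It kept 36, 17 and 45 of 63 for paclitaxel and 5, 7 and 11 of 39 for the combination.

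The number of genes for MBQ-167, paclitaxel, the combination and the interaction was 329, 1733, 916 and 147 with DESeq2 and 392, 1554, 849 and 197 with no filter. With only the groups compared it was 5, 251 and 7 for the 3 drugs against vehicle. With the GC correction it was 491 for paclitaxel and 74 for the combination. The combination against MBQ-167 gave 1 gene with DESeq2 and 4 with no filter, and against paclitaxel 7 with no filter. Leaving out 1 library gave 5 to 42 genes for MBQ-167, 230 to 1139 for paclitaxel, 29 to 416 for the combination, 0 to 0 for the combination against either drug and 2 to 16 for the interaction. It gave 16 to 21 lists for MBQ-167, 15 to 23 for paclitaxel, 18 to 24 for the combination, 6 to 11 for the combination against MBQ-167, 6 to 9 against paclitaxel and 14 to 21 for the interaction.

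Of the 35 lists written in advance and tested, 1 passed with an estimated correlation for each drug group against vehicle and for the interaction, with or without the GC correction, and 0 for the combination against either drug. With fry 5 lists passed for MBQ-167, 13 for paclitaxel, 11 for the combination, 0 for the combination against MBQ-167, 0 against paclitaxel and 2 for the interaction. Lists whose median or test changed direction, with a call in at least 1 of the 2 fits, were B cell markers without paclitaxel 2 (paclitaxel -2.54, interaction 2.93), fibroblast markers without combination 3 (-0.209 against MBQ-167, -0.0599 against paclitaxel, where leaving out 1 library gave up to 0.366), interferon genes in the combination against MBQ-167 without combination 1 (-0.195, and 0.151 without combination 3), mitochondrially encoded transcripts with the GC correction (combination -0.48, paclitaxel -0.398, interaction 0.0683), skeletal muscle markers without vehicle 3 (combination 1.01, interaction -0.407), antigen presentation (-0.0321) and fibroblast markers (0.027) in paclitaxel tumours without vehicle 3, and smooth muscle markers (-0.479, and 0.318 without combination 2) and SRF targets (-0.203) in the combination against paclitaxel without combination 3.

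With the neutrophil marker level as a covariate 22 genes passed for MBQ-167, 326 for paclitaxel, 106 for the combination and 8 for the interaction, against 17, 1033, 336 and 11. Interferon medians were 0.258, 0.681 and 0.274 for MBQ-167, paclitaxel and the combination, against 0.438, 0.845 and 0.539, and the combination call was lost. All 3 T and NK cell calls were lost, with medians of -0.032, -0.247 and -0.191. Hypoxia medians were -0.428, -0.346 and -0.324, against -0.469, -0.405 and -0.423, and all 3 calls at the preset correlation were kept. The median SE of the hypoxia genes grew from 0.203, 0.202 and 0.202 to 0.236, 0.293 and 0.301. Over all genes 6 hypoxia and 17 interferon genes passed with paclitaxel, and 4 and 1 with the combination. The covariate left 0 and 2, and 0 and 0. The GC correction left 2 and 9, and 1 and 1, with medians of -0.408 and 0.88, and -0.427 and 0.483. Neutrophil markers then had 13 and 5, against 13 and 10, with medians of -2.74 and -2.72, against -2.59 and -2.61. Only the interferon median with the combination moved toward 0.

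By their deviations from the group means, all 6 vehicle and combination libraries correlated best with the library of their own number in the other group, a hint that these are paired which comes from the data and not from the design. In none of the other 5 pairs of groups were all 3 correlations over 0.1, and over all pairs they lay between -0.17 and 0.25. With the number as a block 116 of the 124 named values kept their call. In the combination against vehicle 300 genes passed, and Cd177 (-3.09), Olfm4 (-3.15), Actb (-0.59), Tuba1c (-0.55) and 3110067C02Rik (2.81) missed the threshold, while 20 lists passed against 18, with antigen presentation and dendritic cell markers added. With the block and the GC correction together 83 genes and 20 lists passed there, 14 of 39 named values kept their call, and mitochondrially encoded transcripts had -0.491. Depth and n limit what could be seen, since 1.5-fold changes were found for 4.48% to 14.9% of simulated genes.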

Other observations

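The tests of the glucocorticoid-induced and circadian lists were chosen only after the genes that led to them were seen.

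Proliferation and most stromal lists did not pass against vehicle. Medians for MBQ-167, paclitaxel and the combination were -0.01, 0.09 and 0.03 for 22 mitosis genes and -0.08, -0.07 and -0.12 for 22 DNA replication genes, with 0, 2 and 0 mitosis genes and 0, 0 and 0 replication genes past the threshold over all genes. Endothelial markers had 0.03, -0.07 and 0.09, macrophage markers -0.20, -0.30 and -0.20, dendritic cell markers 0.32, 0.36 and 0.62, adipocyte markers -0.10, 0.96 and 0.72, and smooth muscle and pericyte markers -0.14, -0.07 and -0.10. B cell and plasma cell markers had 0.87, 1.40 and 1.11, and skeletal muscle markers -0.42, -1.07 and -0.63. Without paclitaxel 2 the B cell median with paclitaxel turned to -2.54 and passed (camera adjusted p = 0.00486). Without vehicle 3 the skeletal muscle median with the combination turned to 1.01 and passed (camera adjusted p = 0.0232). Fatty acid synthesis genes had 0.08, -0.15 and -0.07, cytokine and chemokine genes 0.04, 0.27 and -0.20, and mitochondrially encoded transcripts -0.04, 0.30 and -0.05. After the GC correction the mitochondrially encoded transcripts had -0.398 with paclitaxel and -0.48 with the combination and passed (camera adjusted p = 0.0297 and 0.000191). Mean and median differed in sign for mitochondrially encoded transcripts in MBQ-167 and combination tumours, for fatty acid synthesis in paclitaxel tumours and for cytokine, endothelial and adipocyte genes in MBQ-167 tumours. Adjusted over the list alone, 1 macrophage gene fell with MBQ-167 and 1 with paclitaxel, 1 dendritic cell gene fell with paclitaxel, 1 cytokine gene fell with the combination, and 0 endothelial, adipocyte, smooth muscle, B cell, skeletal muscle, fatty acid synthesis or mitochondrially encoded genes passed in any of the 3.

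Keratinocyte markers rose in MBQ-167 (median 1.86, 0 of 8 over all genes and 1 adjusted over the list alone, camera adjusted p = 0.00136; adjusted p = 0.318 with an estimated correlation) and combination tumours (1.37, 0 of 8 and 0 alone, camera adjusted p = 0.00784; adjusted p = 0.39 with an estimated correlation). Krt10, a keratin of differentiating epidermis, had 1.73 ± 0.53 with MBQ-167 (adjusted p = 0.191). The MBQ-167 call was lost without MBQ-167 library 2 (0.53) and the combination call without combination 1 (1.05), and the medians were 3.44 and 3.48 without vehicle 1. Skin left on a tumour sample was not recorded. Epithelial markers fell in MBQ-167 tumours (-0.45, 0 of 18 and 2 alone, camera adjusted p = 0.0415; adjusted p = 0.757 with an estimated correlation), with Krt8, a keratin of simple epithelia, at -0.80 ± 0.18 (adjusted p = 0.14). That call was lost without MBQ-167 library 1 (-0.27), MBQ-167 library 2 (-0.31), vehicle 1 (-0.31) and vehicle 3 (-0.08), after the GC correction (-0.45) and with protein-coding genes only (-0.44). The median was -0.89 without MBQ-167 library 3 and -0.88 without vehicle 2. Epithelial medians in paclitaxel (-0.43) and combination tumours (-0.25, mean 0.04) did not pass. Heat shock genes had medians of -0.37, -0.31 and -0.23 with MBQ-167, paclitaxel and the combination, and 5 of 14 fell with paclitaxel, among them Hspb1 (-1.84) and Hspa1b (-1.58). The adjusted p of the list with an estimated correlation was 0.0535, 0.181 and 0.131 over all 39 lists, and 0.011, 0.057 and 0.0494 over the 4 lists added later alone.

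Fkbp5, a gene that glucocorticoids induce, was lower with MBQ-167 (-1.05), paclitaxel (-1.04) and the combination (-0.73), and Per2 had -0.82, -1.07 and 0.02. A candidate explanation is a lower glucocorticoid signal in the drug tumours. Of 13 other glucocorticoid-induced genes, 0, 4 and 2 passed over all genes and the median was -0.72 with MBQ-167, -0.984 with paclitaxel and -0.558 with the combination (-0.36 without vehicle 3). With an estimated correlation the list passed over the 4 added lists alone (adjusted p = 0.011, 0.0148 and 0.0259) and not over all 39 lists (0.0535, 0.0766 and 0.126; at most 0.0877, 0.129 and 0.174 when 1 library was left out). Per1 (-1.14), Mt2 (-1.09), Ddit4 (-1.02) and Mt1 (-0.98) fell with paclitaxel. The list left out Fkbp5 and Dusp1 but holds Ddit4, which was already seen, and Lcn2, which is also on the epithelial list. It also holds the clock gene Per1, and its member Tsc22d3 (-0.971, -0.926 and -0.558) is on the circadian output list too. The glucocorticoid and circadian lists are therefore not fully separate. A shift in the time of collection might also move Per2, but 12 circadian output genes had medians of -0.13, -0.286 and -0.194 and did not pass (camera adjusted p = 0.0567, 0.0709 and 0.3), and without 1 library the MBQ-167 median lay between -0.207 and 0.0147 and the combination median between -0.259 and -0.0662, so such a shift cannot be told apart from none with 12 genes that go both ways. The hypothesis was found and tested on the same libraries, and neither the hour of collection nor hormone levels are in the labels.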
